A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

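Messenger RNA levels were measured in Saccharomyces cerevisiae strain BY4741, a haploid laboratory strain that lacks URA3, LEU2 and MET17. Per the labels' protocols, saturated cultures in rich glucose medium at 30 °C received 0.05 mM TFM in 2% isopropanol, the solvent, for 1, 2 or 4 h. The labels give TFM only as an abbreviation; it is the usual short name of a nitrophenol lampricide known as an uncoupler of oxidative phosphorylation. Controls were taken just before treatment, with solvent alone, and stand for time zero. No solvent control was taken at 1, 2 or 4 h, so time after time zero and exposure to TFM cannot be separated in any comparison with the controls. The 8 arrays came from 7 RNA samples: 2 controls, 2 at 1 h, 2 at 2 h and 1 at 4 h, whose 2 arrays are technical. The 2 arrays at 4 h were averaged and counted as n = 1, and that sample was assumed to vary like the other groups.

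Per the labels' protocols, total RNA was purified on silica columns, copied into biotin-labelled cRNA with a commercial kit, fragmented, and hybridised to a 1-colour Affymetrix yeast array. The deposited values are on the log2 scale as judged from their range, since the log base is not given in the sources used here. Per the submitters' processing notes they were made by RMA, which corrects background, normalises arrays to a shared distribution and summarises the probes of each probe set; no version is named. Since arrays are brought to a shared distribution before the probes are summarised, a change in total mRNA per cell would not appear in these values. It also holds down differences among dim probe sets. Array medians lay between 11.03 and 11.11, but the low ends differed. The 5th percentile was 7.91 and 8.20 in the controls and 8.39 and 8.40 at 1 h.

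The table held 5814 probe sets. Of these 5498 had 1 gene name, 0 had several and 316 had none, of which 98 were control or reporter probe sets. Names came from the platform's annotation, and 12 gene symbols were updated. For 47 genes with more than 1 probe set, the one with the highest mean was kept, which left 5449 genes tested. No genome annotation was used here, so no coordinates are given. No other-species probe sets were found by name, so the background was set by the fallback fixed beforehand, the 25th percentile of all probe sets, 10.02 on the log2 scale. Genes with a mean below it are called dim. The probe sets of the genes that the strain lacks averaged 3.79 (URA3), 5.89 (LEU2) and 4.58 (MET17), at percentiles 0.48, 1.24 and 0.88. Many dim genes lay well above these probe sets. Whether other probe sets read higher without their transcript cannot be told from these, so dim genes are not shown to be expressed. Arrays carry no read depth, and their number limits the precision.

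Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 7 RNA samples, so that the 4 groups share 1 estimate of spread (3 residual degrees of freedom, prior degrees of freedom 3.36, prior SD 0.096). P-values were adjusted by Benjamini-Hochberg within each comparison, and genes under 0.05 passed. The comparisons, fixed before the data were examined, were each time point against control, the mean of 1 h and 2 h against control, the differences between time points, and an F test over the 3 time points. Errors on log2 changes are limma's standard errors. The labels call the replicates biological but do not say whether they came from separate cultures, so p-values measure only the spread between these samples. On simulated values with known changes in 200 of 5449 genes, limma found 87.8% of 2-fold changes at 1 h, 88.1% at 2 h and 78.8% at 4 h. False calls per run were 9.9, 9.4 and 7. The simulation used independent noise, 1 spread per gene for all groups and the same change at every time. Shifts shared by an array and unequal spread between groups were left out, so these rates need not hold for the real samples.

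There were 33 fixed gene lists, on respiration and mitochondria (TCA cycle, respiratory chain, ATP synthase, mitochondrially encoded genes, mitochondrial ribosomal proteins, retrograde response), carbon use (glycolysis and fermentation, hexose transporters, gluconeogenesis with the glyoxylate cycle, peroxisomal beta-oxidation, trehalose and glycogen), stress (general stress, stationary phase, heat shock chaperones, proteasome, oxidative stress, aryl-alcohol dehydrogenases with nitroreductases, multidrug resistance, weak acid response, proton pumps), growth (ribosomal proteins, ribosome biogenesis), nutrients (amino acid biosynthesis, sulfur and methionine, nitrogen catabolite repression, purine and uridine nucleotides, phosphate, iron, ergosterol) and cell structure or fate (cell wall, autophagy, histones with cyclins, meiosis and sporulation). Some genes are in more than 1 list. 32 lists were tested, since 0 mitochondrially encoded genes were measured. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With an estimated correlation camera uses the 3 residual degrees of freedom, so hardly any list could pass, even one with a low correlation. Members past the test were counted over all genes and adjusted over the list alone.

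Genes were named by a fixed rule: in each comparison with control, the 8 largest rises and falls among genes past the test whose treated arrays all lay outside the range of the controls, whose brighter group mean exceeded the background and which have a standard name; up to 4 members of each described list; the 5 largest differences each way between time points; and PDR5, SNQ2, PDR12, HSP12, CIT2, PMA1 and the genes lacking in the strain. Not every list member the rule allows is named. Ribosomal protein genes whose names end in A or B have a paralogous copy, and which copy changed was not tested. Alternatives planned beforehand were the replicate number as a block, quantile normalisation or median centring over the tested genes, a filter on dim genes, a trended or robust prior, the mean of probe sets, a fit of only the groups compared, a random block over the 8 arrays, leaving out each array, and a 2-fold threshold. A filter at the level of the lacking genes, and camera on differences between time points, were added after seeing the data. Groups of 2 are too small for tests of single outlying samples or for other splits of the samples.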

Results

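Expression of 5449 yeast genes was measured on 8 arrays from 7 RNA samples: controls at time zero (n = 2), and cultures after 1 h (n = 2), 2 h (n = 2) and 4 h (n = 1, with 2 technical arrays) in 0.05 mM TFM. The question, from the series title, is how yeast respond to TFM over time. Root mean square SDs between samples were 0.16 in controls, 0.17 at 1 h and 0.085 at 2 h on the log2 scale, and 0.056 between the technical arrays at 4 h. The F test over the time points called 355 genes, 89 of them with at least a 2-fold change. The count was 836 without 1 h replicate 1, 1 without either 2 h replicate and 610 with a trended prior. Log2 changes are given with limma's standard error (SE).

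Measures outside the genes tested also moved with time. The median of 17 ribosomal RNA control probe sets was 9.76 and 9.97 in the controls, 10.5 and 11.8 at 1 h, 11.4 and 13.0 at 2 h, and 12.2 and 12.1 on the 4 h arrays. The dimmest 10% of genes had a median change of 0.24 at 1 h, against -0.05 at 2 h and -0.06 at 4 h, and it differed by 0.15 between the control replicates. The mean difference between 3' and 5' control probe sets was 1.37 in control replicate 1 and 1.11 in control replicate 2. It was 1.21 and 1.14 at 1 h, 1.11 and 1.13 at 2 h, and 1.20 and 1.17 on the 4 h arrays. Control replicate 1 thus had the highest difference of the 8 arrays. It also had the lowest 5th percentile, 7.91, and the lowest ribosomal RNA signal. The probe sets of URA3, LEU2 and MET17, which the strain lacks, changed by -0.31, -0.11 and 0.01 at 1 h, and none passed the test.

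**Figure D1:**
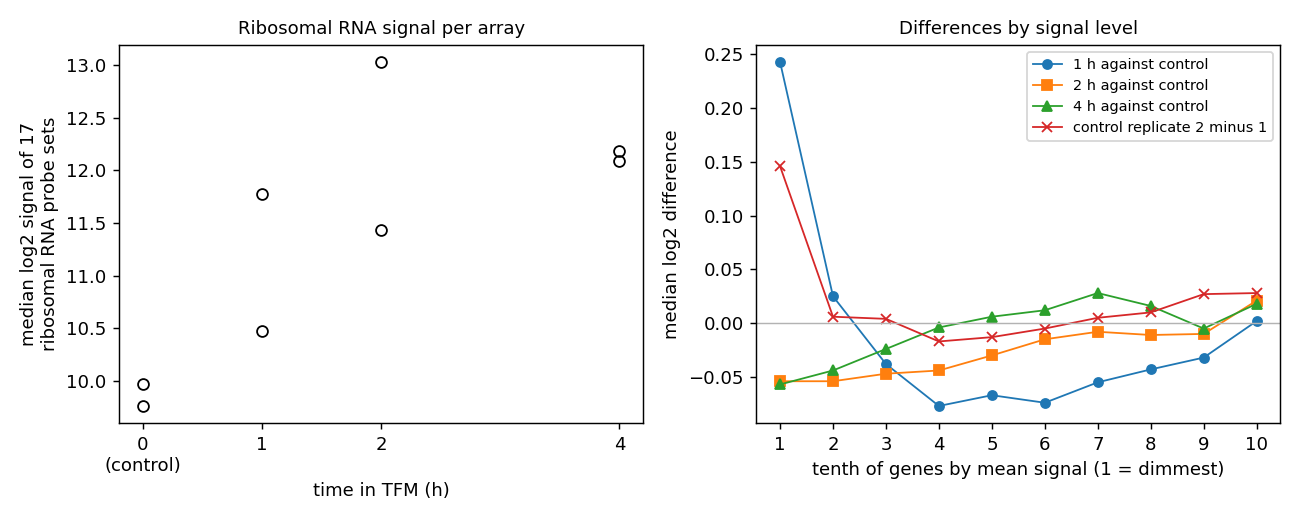
Left: median log2 signal of 17 ribosomal RNA probe sets, 1 point per array, against hours in TFM; the controls lie at 9.76 and 9.97, below every treated array. Right: median log2 difference in 10 equal bins of genes by mean signal, for each time against control and between the controls; the dimmest bin lies at 0.24 at 1 h.

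After 1 h of TFM, 28 of 95 ribosome biogenesis genes rose (adjusted p = 0.64 for the list with an estimated correlation), and STL1, GPD1 and CTT1 were among the genes that fell. SPB1, a methyltransferase of large-subunit assembly, rose from 9.13 ± 0.40 (SD, n = 2) to 10.63 ± 0.15 (SD, n = 2), by 1.49 (SE 0.19). STL1, which imports glycerol, fell from 13.31 ± 0.34 (SD, n = 2) to 11.73 ± 0.24 (SD, n = 2). GPD1, which makes glycerol phosphate, fell by 0.97 (SE 0.14), and CTT1, the cytosolic catalase, fell by 0.91 (SE 0.17). In limma 189 genes were higher and 83 lower, and 67 and 5 of these by at least 2-fold. Of these, 135 of the higher and 35 of the lower were among 1319 dim genes, as were SPB1 and, of the genes named next, LDS2, RPA43 and PAU21.

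The other leading rises at 1 h were LDS2, a spore wall gene, by 1.72 (SE 0.24, adjusted p = 0.0262), RPA43, a subunit of RNA polymerase I, by 1.36 (SE 0.19), POL30, the sliding clamp of DNA replication, by 1.30 (SE 0.12, adjusted p = 0.0168), and PUF6, an RNA-binding protein of ribosome assembly, by 1.24 (SE 0.21). PAU21, PAU4 and PAU9 rose by 1.44, 1.41 and 1.25, but their family has near-identical copies, so which member changed is uncertain. Among the other leading genes, PHM7 fell by 1.99 (SE 0.31), FMP45 by 1.65 (SE 0.20), FMP48 by 1.45 (SE 0.21), the cell wall mannoprotein CWP1 by 1.00 (SE 0.16) and FIT1, which holds iron-siderophores at the wall, by 0.96 (SE 0.18). The efflux pump genes PDR5 (0.09) and SNQ2 (-0.08), the acid pump gene PDR12 (0.40), HSP12 (0.00), CIT2 (0.05) and PMA1 (0.02), the plasma membrane proton pump, did not pass.

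Calls at 1 h rested on single libraries, on the estimate of spread shared with the 2 h group and on scaling. Leaving out control replicate 1 left 1 gene higher and 0 lower, 1 h replicate 2 left 50 and 9, and either 2 h replicate left 24 and 3, while leaving out 1 h replicate 1 gave 430 and 575; of the 51 calls on named genes, 0 passed without control replicate 1. The share of calls that were higher was 69.5%, against 82.3% (246 and 53) after median centring and 54.7% (173 and 143) after quantile normalisation. Over genes above the 25th percentile 63 were higher, and a fit of only the groups compared gave 24 and 3. As in that fit, leaving out a 2 h replicate takes the 2 h spread out of the shared estimate. That SD was 0.085, against 0.16 in controls and 0.17 at 1 h. Control replicate 1, without which the fewest calls passed, had the highest 3' minus 5' difference of the 8 arrays, 1.37.

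Ribosome biogenesis genes had the largest median of the 32 lists tested at 1 h: 28 of 95 rose and 0 fell, with 71 adjusted over the list alone and a median of 0.45, beside the raised ribosomal RNA signal and the shift of dim genes. Camera gave adjusted p = 5.62e-29, and adjusted p = 0.64 with an estimated correlation, while fry gave adjusted p = 0.0533. Ribosomal protein genes had 3 of 127 rise (2 adjusted over the list alone), RPL36A by 0.55 and RPL37A by 0.47 among them, with a median of 0.08 and camera's adjusted p = 0.00294 (adjusted p = 0.706 with an estimated correlation). Of 25 histone and cyclin genes 1 rose (4 adjusted over the list alone), with a median of 0.17 and adjusted p = 0.0253 (adjusted p = 0.64 with an estimated correlation). Of 25 meiosis genes 6 rose and 1 fell (9 and 2 adjusted over the list alone), including the kinases SPS1 by 1.15 and MEK1 by 0.88, both dim, with adjusted p = 0.0408. Of 19 hexose transporter genes 2 rose (5 up and 1 down adjusted over the list alone), with adjusted p = 0.0386: HXT8 by 1.69 and STD1, a glucose-signalling gene and not a transporter, by 0.55, both dim. Both lists had adjusted p = 0.64 with an estimated correlation. All of these calls but that of ribosome biogenesis were lost when 1 array was left out. The ribosomal protein median was 0.04 (adjusted p = 0.0678) without control replicate 1, 0.02 (adjusted p = 0.442) without 1 h replicate 2 and 0.14 without 1 h replicate 1. That of histones and cyclins was 0.16 (adjusted p = 0.145) without 1 h replicate 1. That of meiosis was 0.11 (adjusted p = 0.056) without control replicate 2, 0.05 (adjusted p = 0.0687) without 1 h replicate 1 and 0.14 (adjusted p = 0.0757) without 1 h replicate 2. That of hexose transporters was 0.17 (adjusted p = 0.105) without control replicate 2, 0.16 (adjusted p = 0.327) without 1 h replicate 1 and 0.39 without 1 h replicate 2. It had the opposite sign, -0.18, over genes above the 25th percentile. After quantile normalisation the hexose transporter and meiosis calls were lost (0.12, adjusted p = 0.0951, and 0.10, adjusted p = 0.407), as they were after median centring (0.23, adjusted p = 0.0875, and 0.15, adjusted p = 0.0945). Centring gave a ribosomal protein median of 0.14.

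Lists shifted down at 1 h were sulfur and methionine metabolism, gluconeogenesis, cell wall, trehalose and glycogen, and aryl-alcohol dehydrogenases with nitroreductases. Of 30 sulfur genes 3 fell (3 adjusted over the list alone), including MET28 by -0.56 and MET8 by -0.50, with a median of -0.25 and adjusted p = 0.0101 (adjusted p = 0.706 with an estimated correlation). Of 21 gluconeogenesis genes 3 fell (5 adjusted over the list alone): ACS1, an acetyl-CoA synthetase, by -0.76, ICL1, isocitrate lyase, by -0.52 and ADH2, which oxidises ethanol, by -0.45, with adjusted p = 0.0357. Of 35 cell wall genes 3 fell and 2 rose (6 and 2 adjusted over the list alone), with CWP1 and PIR3 (-0.54) down and SCW10 (0.50) up, and adjusted p = 0.0421. In limma 0 of 17 trehalose and glycogen genes passed, also adjusted over the list alone, and TPS2 stood at -0.47; camera gave a median of -0.20 and adjusted p = 0.00665. Of 10 aryl-alcohol dehydrogenase and nitroreductase genes 0 passed and 6 fell adjusted over the list alone, with a median of -0.26 and adjusted p = 0.021; ADH7 stood at -0.43. These last 4 lists each had adjusted p = 0.64 with an estimated correlation. Of these calls, those of sulfur, gluconeogenesis and cell wall were lost when 1 array was left out. The sulfur median was -0.10 (adjusted p = 0.137) without 1 h replicate 2 and -0.40 without 1 h replicate 1. That of gluconeogenesis was -0.06 (adjusted p = 0.327) without 1 h replicate 1. That of cell wall was -0.10 (adjusted p = 0.0678) without control replicate 1, -0.14 (adjusted p = 0.074) without 1 h replicate 1, -0.08 (adjusted p = 0.12) without 1 h replicate 2 and -0.16 without control replicate 2. The trehalose and glycogen median was -0.32 without 1 h replicate 1 and -0.10 (adjusted p = 0.0478) without 1 h replicate 2. Quantile normalisation ended the calls of gluconeogenesis (-0.10, adjusted p = 0.0563) and cell wall (-0.10, adjusted p = 0.0687), and median centring left medians of -0.05 and -0.04 (both adjusted p = 0.0456). Over genes above the 25th percentile the calls of cell wall (-0.09, adjusted p = 0.218) and of aryl-alcohol dehydrogenases with nitroreductases (-0.26, adjusted p = 0.132) were lost.

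Camera called no shift at 1 h in the other 22 lists tested (adjusted p from 0.0636 to 0.829). The only falls were CIT3 (-0.48) in the TCA cycle, NDE2 (-0.61) in the respiratory chain, PDC6 (-0.60) in glycolysis and fermentation, CTT1 in general stress, SNZ1 (-0.40) in stationary phase, MDJ1 (-0.38) in heat shock chaperones, PDR15 (-0.47) and PDR3 (-0.36) in multidrug resistance, and 3 iron genes, including FIT1 and MRS4 (-0.52). HES1 (1.58) in ergosterol and ATG16 (1.06) in autophagy, both dim, rose. Adjusted over the list alone, 1 fell in each of the TCA cycle, respiratory chain and glycolysis, 2 in multidrug resistance, 3 in iron and 0 in heat shock chaperones. By that measure 1 rose and 2 fell in general stress, 1 rose and 3 fell in stationary phase, 1 rose in ergosterol and 2 in autophagy. In limma 0 members passed in ATP synthase, mitochondrial ribosomal proteins, retrograde response, peroxisomal beta-oxidation, proteasome, oxidative stress, weak acid response, proton pumps, amino acid biosynthesis, nitrogen catabolite repression, purine and uridine nucleotides and phosphate. Over all genes 1499 had an unadjusted p under 0.05 at 1 h.

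**Figure D2:**
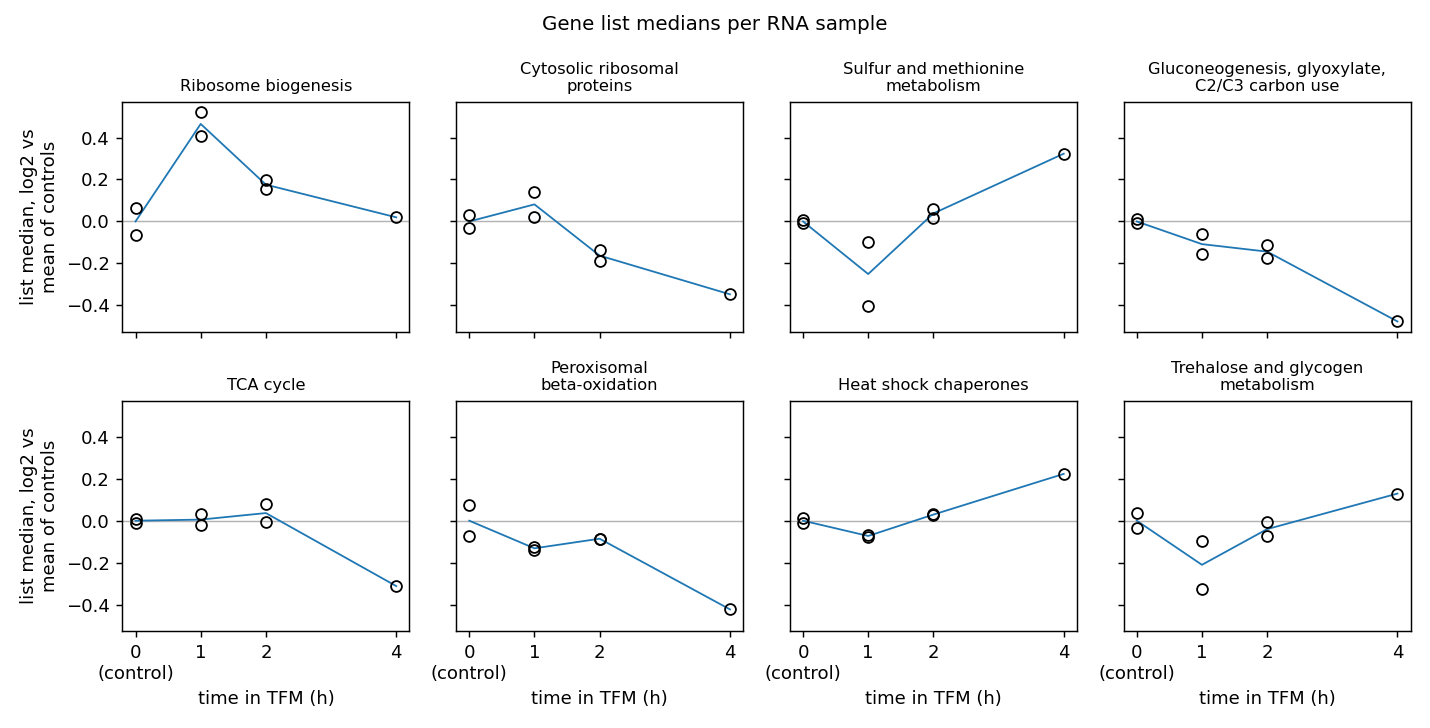
Median log2 difference from the mean of the controls for 8 gene lists, against hours in TFM (0 is the control). Circles are RNA samples (n = 2, 2, 2 and 1) and lines join their means; ribosome biogenesis stood at 0.41 and 0.52 at 1 h, and ribosomal proteins at -0.35 at 4 h.

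After 2 h few genes passed, and most of those were lower. STL1 fell by 1.71 (SE 0.18, adjusted p = 0.0486), FMP45 by 1.96 (SE 0.20) and CWP1 by 1.58 (SE 0.16). ADE17, an enzyme of purine synthesis, fell by 1.00 (SE 0.08, adjusted p = 0.0473), and SPO20, a dim sporulation gene, by 0.95 (SE 0.09). ECM13 alone rose, from 11.55 ± 0.12 (SD, n = 2) to 12.46 ± 0.01 (SD, n = 2). Limma called 1 gene higher and 5 lower, of which 0 and 3 by at least 2-fold, and 671 had an unadjusted p under 0.05. No gene was called without 2 h replicate 1 or without 2 h replicate 2, 0 higher and 2 lower without control replicate 1, 1 and 20 without control replicate 2, and 4 and 11 without either 1 h replicate. The higher share was 16.7%, against 33.3% (1 and 2) after median centring, and quantile normalisation left 0 and 0. A trended prior gave 10 and 33, genes above the 25th percentile 7 and 20, and a fit of only the groups compared 4 and 11.

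Lists shifted at 2 h with few members past the test. The ribosome biogenesis median was 0.17 (0 of 95 passed in limma, 5 rose adjusted over the list alone; adjusted p = 7.57e-15) and the ribosomal protein median was -0.16 (0 of 127 passed, 21 fell adjusted over the list alone; adjusted p = 2.77e-12). With an estimated correlation their adjusted p was 0.473 and 0.559, and by fry 0.292 and 0.224. NSR1, the yeast nucleolin, stood at 0.69 and NOG1 at 0.68, and the ribosomal protein gene RPS0A at -0.64. Gluconeogenesis had a median of -0.13 (0 of 21 passed, 6 fell adjusted over the list alone; adjusted p = 0.00434), with adjusted p = 0.473 with an estimated correlation. Of 25 meiosis genes 1 fell, SPO20 (5 adjusted over the list alone), with a median of -0.22 and adjusted p = 3.12e-05; of 26 purine and uridine genes 1 fell, ADE17 (2 adjusted over the list alone), with a median of -0.09 and adjusted p = 0.0314. Both had adjusted p = 0.404 with an estimated correlation. The ribosome biogenesis median was 0.10 without control replicate 1 and 0.29 without control replicate 2. The purine and uridine call was lost without control replicate 2 (median -0.11, adjusted p = 0.123) and without 2 h replicate 1 (-0.07, adjusted p = 0.141), and its median was -0.05 after median centring.

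In limma 0 genes passed in the other lists shifted at 2 h. Medians were 0.12 for the respiratory chain (adjusted p = 0.000109), 0.12 for the retrograde response with 11 of 11 genes positive (adjusted p = 0.00078), 0.15 for the weak acid response (adjusted p = 0.00145), 0.08 for ATP synthase (adjusted p = 0.00494), 0.05 for nitrogen catabolite repression (adjusted p = 0.0114), 0.02 for histones and cyclins (adjusted p = 0.0336) and -0.07 for mitochondrial ribosomal proteins (adjusted p = 0.0423). With an estimated correlation the adjusted p was 0.591 for the respiratory chain, 0.714 for ATP synthase and mitochondrial ribosomal proteins, 0.473 for histones and cyclins and 0.404 for the other 3. Adjusted over the list alone, 1 nitrogen gene and 1 histone or cyclin gene rose and 0 passed in the others. In the weak acid list YRO2 stood at 0.64 and PDR12 at 0.66. Beyond CWP1 of the cell wall list, 0 members passed in the 20 lists not shifted. Adjusted over the list alone, 3 cell wall genes, 3 iron, 2 stationary phase, 2 phosphate and 1 TCA cycle gene fell, and 1 proton pump gene rose. Of the lists shifted, the respiratory chain had a median of 0.07 without control replicate 1 and 0.06 without 2 h replicate 1. Its samples at 2 h stood at 0.16 and 0.06. ATP synthase had 0.05 (adjusted p = 0.136) without control replicate 1, 0.04 (adjusted p = 0.0879) without 2 h replicate 1 and 0.14 without control replicate 2. Mitochondrial ribosomal proteins had -0.04 without control replicate 2 (adjusted p = 0.511) or 2 h replicate 2 (adjusted p = 0.228), and -0.07 (adjusted p = 0.0564) without either 1 h replicate. Histones and cyclins had 0.03 without control replicate 1 (adjusted p = 0.179) or 2 h replicate 1 (adjusted p = 0.0631), 0.02 (adjusted p = 0.0581) without either 1 h replicate, 0.15 without control replicate 2 and 0.09 without 2 h replicate 2. Nitrogen catabolite repression had 0.06 (adjusted p = 0.123) without control replicate 2 and 0.08 without 2 h replicate 2. Median centring ended the calls of mitochondrial ribosomal proteins (-0.04, adjusted p = 0.0773) and of histones and cyclins (0.05, adjusted p = 0.0689), and gave 0.08 for nitrogen catabolite repression. Quantile normalisation gave 0.07 for the nitrogen list and 0.04 for histones and cyclins, which had 0.14 over genes above the 25th percentile.

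After 4 h, in the single RNA sample, 11 of 21 gluconeogenesis and glyoxylate genes and 37 of 127 ribosomal protein genes fell, and 6 of 30 sulfur and methionine genes rose. With an estimated correlation the lists had adjusted p = 0.446, 0.452 and 0.452. ADH2 stood at 11.51 against 14.29 ± 0.03 (SD, n = 2) in the controls, and fell by 2.78 (SE 0.11, adjusted p = 0.000562). ICL1 fell by 1.86 (SE 0.10, adjusted p = 0.00185), RPL22A by 1.68 (SE 0.12) and RPS9B by 1.69 (SE 0.12). STR3, which makes homocysteine from cystathionine, rose by 1.14 (SE 0.14, adjusted p = 0.0177), and OPT1, a glutathione transporter outside the sulfur list, by 1.07 (SE 0.12). In limma 40 genes were higher and 203 lower (7 and 35 by at least 2-fold), and 9 and 43 of these were dim. Quantile normalisation gave 25 and 125, and 71 were higher with a trended prior and 64 over genes above the 25th percentile.

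The other leading rises at 4 h were NSR1 by 1.28 (SE 0.10), RRP14 by 1.23 (SE 0.24) and NOG1 by 0.84 (SE 0.11), all of ribosome assembly, the methionine permease gene MUP3 by 0.97 (SE 0.13), the uridine permease gene FUI1 by 0.96 (SE 0.11) and the nucleolar gene SRP40 by 0.86 (SE 0.17). The other leading falls were STL1 by -1.96 (SE 0.22), RKI1, an isomerase of the pentose phosphate pathway, by -1.74 (SE 0.09), INO1, which starts inositol synthesis, by -1.47 (SE 0.10) and GPP1, a glycerol phosphatase, by -1.45 (SE 0.18). PDR5 (0.34), SNQ2 (0.11), PDR12 (-0.27), HSP12 (0.06), CIT2 (0.12) and PMA1 (-0.53, adjusted p = 0.0559) did not pass. The counts rested on few samples: without either 2 h replicate 2 genes were higher and 16 lower, without control replicate 1 3 and 39, without control replicate 2 11 and 73, and without either 1 h replicate 82 and 271. Of 45 calls on named genes, 13 passed without either 2 h replicate, 19 without control replicate 1 and 29 without control replicate 2.

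At 4 h 37 of 127 ribosomal protein genes fell and 0 rose (70 fell and 1 rose adjusted over the list alone), with a median of -0.35 and camera's adjusted p = 1.83e-24, in a sample whose ribosomal RNA signal exceeded both controls. RPL8A fell by 1.36 and RPS0A by 1.30. Like RPL22A and RPS9B they have a paralogous copy, and which copy changed was not tested. In gluconeogenesis and the glyoxylate cycle 11 of 21 fell (13 adjusted over the list alone), with a median of -0.48 and adjusted p = 1.74e-10; beside ADH2 and ICL1 these included SFC1, a mitochondrial carrier, by 1.44 and ACS1 by 1.38. In the TCA cycle 3 of 18 fell (9 adjusted over the list alone), including CIT3 by 0.64 and aconitase ACO1 by 0.56, with a median of -0.31 and adjusted p = 2.1e-06. In peroxisomal beta-oxidation 8 of 18 fell (9 adjusted over the list alone), including the catalase CTA1 by 0.96 and the acyl-CoA oxidase POX1 by 0.94, with a median of -0.42 and adjusted p = 0.000125. Of 67 mitochondrial ribosomal protein genes 2 fell (2 adjusted over the list alone), MRPL20 by 0.55 among them, with adjusted p = 0.00154. With an estimated correlation the adjusted p was 0.446 for gluconeogenesis, 0.485 for mitochondrial ribosomal proteins and 0.452 for the other 3.

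In sulfur and methionine metabolism 6 of 30 genes rose and 0 fell at 4 h (8 adjusted over the list alone), including MUP1, the main methionine permease, by 0.83, with a median of 0.32 and adjusted p = 1.67e-08 (adjusted p = 0.452 with an estimated correlation). Heat shock chaperones had 24 of 24 values above 0 with a median of 0.22 (adjusted p = 6.19e-06, and adjusted p = 0.446 with an estimated correlation), but in limma 0 passed, also adjusted over the list alone; SSE1 stood at 0.35 and HSP104 at 0.31. By fry, 9 lists moved at 4 h, gluconeogenesis (adjusted p = 0.00881), ribosomal proteins (0.0274) and heat shock chaperones (0.0274) among them. Fry called 0 lists at 1 h and 0 at 2 h. Between time points it called 1 at 2 h against 1 h, 11 at 4 h against 1 h and 1 at 4 h against 2 h. Sulfur and mitochondrial ribosomal proteins, which camera called, did not pass fry (adjusted p = 0.109 for each). Fry also called stationary phase (0.0274), nitrogen catabolite repression (0.0238), purine and uridine nucleotides (0.011) and meiosis (0.0274), where camera called no shift.

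Camera called no shift at 4 h in the other 25 lists. Of 95 ribosome biogenesis genes 4 rose and 2 fell, NSR1, RRP14 and NOG1 among the former and RRP1 (-1.08) among the latter. In the stationary phase list 5 fell, including SNZ3 (-1.04), SIP18 (-0.83) and SNZ1 (-0.69), in cell wall 7 fell, including SCW10 (-1.11) and CWP1 (-1.01), in amino acid biosynthesis 5 fell (7 adjusted over the list alone), including ASN2 (-0.87), and in ergosterol 4 fell (7 adjusted over the list alone), including ERG4 (-0.84). In iron 2 fell (3 adjusted over the list alone), including SIT1 (-1.12), in purine and uridine nucleotides 2 fell (3 adjusted over the list alone), ADE17 (-1.30) and IMD3 (-0.78), and in nitrogen catabolite repression UGA4 (0.64) and DAL80 (0.65) rose and 1 fell. Falls numbered 2 each in phosphate, meiosis, general stress and oxidative stress, and 1 each in ATP synthase, retrograde response, proteasome, multidrug resistance and histones with cyclins. Adjusted over the list alone 1 oxidative stress gene also rose, and the other counts in this paragraph were the same. In limma 0 members passed in the respiratory chain, glycolysis, hexose transporters, trehalose and glycogen, aryl-alcohol dehydrogenases, weak acid response, proton pumps and autophagy, and 1079 genes had an unadjusted p under 0.05.

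**Figure D3:**
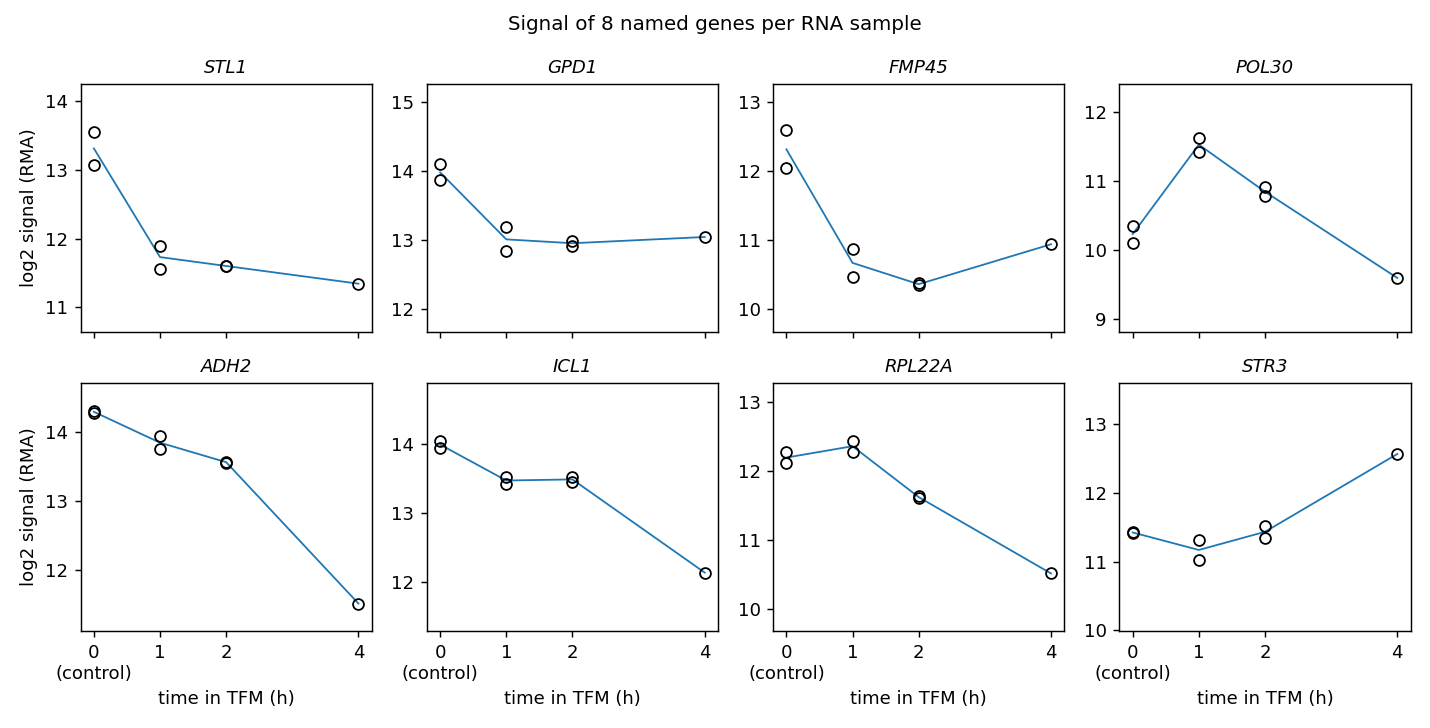
Log2 RMA signal of 8 genes against hours in TFM (0 is the control). Circles are RNA samples (n = 2, 2, 2 and 1, the last the mean of technical arrays), lines join group means, and every panel spans the same log2 range; ADH2 stood at 14.29 in the controls and 11.51 at 4 h.

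In the mean of 1 h and 2 h against control, which uses replicated samples on both sides, 17 genes were higher and 19 lower (1 and 5 by at least 2-fold), and 1076 had an unadjusted p under 0.05. The higher share was 47.2%, against 63.6% (7 and 4) after median centring. A trended prior gave 34 and 41, and genes above the 25th percentile 26 and 35. In limma no gene passed without control replicate 1 or without either 2 h replicate; the counts were 8 and 9 without 1 h replicate 2, 136 and 147 without 1 h replicate 1, and 113 and 75 without control replicate 2.

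From 1 h to 2 h most differences were falls among dim genes. RNP1 changed by -1.96 (SE 0.28), ECM11 by -1.96 (SE 0.32), PHO92 by -1.96 (SE 0.34) and GAT3 by -1.86 (SE 0.30), all dim. PFS1 also passed, but its mean at 2 h, 4.35, lay below the mean of the lacking LEU2, 5.89, so the size of its difference is uncertain. INO1 was higher by 1.20 (SE 0.09, adjusted p = 0.0139), the wall gene PIR3 by 0.73 (SE 0.11), COQ6, of ubiquinone synthesis, by 0.54 (SE 0.07), YER053C-A by 0.53 (SE 0.09) and CPD1 by 0.51 (SE 0.08). Limma called 7 genes higher and 137 lower (1 and 41 by at least 2-fold), and 96 of the lower ones were dim. The higher share was 4.9%, against 32.5% (50 and 104) after quantile normalisation. With a trended prior 21 were higher, and over genes above the 25th percentile 52 were lower. Leaving out 1 h replicate 1 gave 259 and 304, 1 h replicate 2 gave 1 and 24, either control gave 10 and 257, and either 2 h replicate left 0 and 0, with 1213 genes at an unadjusted p under 0.05 in the full set.

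By camera, added here after the data were seen, 6 lists shifted between 1 h and 2 h, all with an adjusted p of 0.235 or more with an estimated correlation. Of ribosomal protein genes 10 fell (49 adjusted over the list alone; median -0.23, adjusted p = 2.01e-19), of ribosome biogenesis genes 11 fell (27 adjusted over the list alone; median -0.25, adjusted p = 2.45e-12) and of meiosis genes 8 fell (15 down and 1 up adjusted over the list alone; median -0.52, adjusted p = 5.37e-08). Medians were 0.25 for sulfur (5 rose adjusted over the list alone; adjusted p = 0.000653), 0.18 for trehalose and glycogen (adjusted p = 0.00126) and 0.12 for heat shock chaperones (adjusted p = 0.00188), with 0 members past limma over all genes in these and, in the last 2, 0 adjusted over the list alone.

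Between 1 h and 4 h, 13 of 30 sulfur genes rose, 61 of 127 ribosomal protein genes fell, and 32 of 95 ribosome biogenesis genes fell and 1 rose. Each list had adjusted p = 0.416 with an estimated correlation. Of the sulfur genes STR3 was higher by 1.39 (SE 0.14), the sulfate permease gene SUL2 by 1.37 (SE 0.26) and MUP1 by 1.11 (SE 0.13). Outside that list OPT1 was higher by 1.40 (SE 0.12) and YKL068W-A by 1.24 (SE 0.12). ADH2 was lower by -2.33 (SE 0.11, adjusted p = 0.0017), and so were PHO92 by -2.01 (SE 0.42) and YDL159W-A by -1.98 (SE 0.47), both dim. MF(ALPHA)1, an alpha-factor gene of the opposite mating type, and PFS1 also passed. At 4 h they stood at 5.51 and 4.32, below the mean of the lacking LEU2 (5.89), so the size of their differences is uncertain. Limma called 174 higher and 465 lower (112 by at least 2-fold, 7 of them higher), and the higher share was 27.2%, against 38.5% (243 and 388) after quantile normalisation. With a trended prior 334 were higher, and over genes above the 25th percentile 284. Without either 2 h replicate 7 were higher and 93 lower, and without 1 h replicate 1 649 and 678.

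Of 13 lists shifted between 1 h and 4 h, ribosomal proteins had 61 fall (88 down and 1 up adjusted over the list alone; median -0.45, adjusted p = 1.37e-24), ribosome biogenesis 32 fall and 1 rise (50 and 1 adjusted over the list alone; median -0.44, adjusted p = 2.3e-11) and sulfur 13 rise (23 adjusted over the list alone; median 0.61, adjusted p = 2.56e-10). Each had adjusted p = 0.416 with an estimated correlation. Of heat shock chaperones 4 rose (8 adjusted over the list alone), including MDJ1 by 0.61, with adjusted p = 4.12e-06 and adjusted p = 0.416 with an estimated correlation. Gluconeogenesis (9 fell, 11 adjusted over the list alone; adjusted p = 9.22e-06), the TCA cycle (4 fell, 10 adjusted over the list alone; 4.34e-05), meiosis (8 fell and 1 rose, 13 and 1 adjusted over the list alone; 0.000528), histones with cyclins (4 fell, 4 down and 1 up adjusted over the list alone; 0.0101) and glycolysis (0 passed in limma; 0.0451) also had adjusted p = 0.416 with an estimated correlation. Trehalose and glycogen had 2 rise (7 adjusted over the list alone; adjusted p = 0.00186), ATP synthase 2 fall (3 adjusted over the list alone; 0.00639), mitochondrial ribosomal proteins 2 fall (2 adjusted over the list alone; 0.00738) and peroxisomal beta-oxidation 8 fall (10 adjusted over the list alone; 0.012). With an estimated correlation these were adjusted p = 0.451, 0.632, 0.574 and 0.492.

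Between 2 h and 4 h, ADH2 was lower by -2.05 (SE 0.11, adjusted p = 0.00258), INO1 by -1.93 (SE 0.10), RNR1, of deoxyribonucleotide synthesis, by -1.45 (SE 0.21) and ICL1 by -1.35 (SE 0.10). MF(ALPHA)1 also passed, with its 4 h value of 5.51 below the mean of the lacking LEU2 (5.89). STR3 was higher by 1.13 (SE 0.14), OPT1 by 0.89 (SE 0.12), YKL068W-A by 0.88 (SE 0.12), MUP3 by 0.86 (SE 0.13) and SNU13, a core protein of box C/D particles, by 0.67 (SE 0.09). Limma called 5 higher and 42 lower (1 and 17 by at least 2-fold), and 0 and 0 without either 2 h replicate, with 658 genes at an unadjusted p under 0.05 in the full set. The counts were 11 and 65 without either 1 h replicate and 2 and 17 without either control. A trended prior gave 9 and 99, genes above the 25th percentile 11 and 80, and 3 were higher after quantile normalisation. Of 13 lists shifted, gluconeogenesis had 6 of 21 fall (11 adjusted over the list alone; median -0.33, adjusted p = 3.51e-12) and ribosomal proteins 7 of 127 (28 down and 1 up adjusted over the list alone; median -0.22, adjusted p = 1.5e-19). With an estimated correlation their adjusted p was 0.431 and 0.451. Sulfur had 2 rise (8 adjusted over the list alone; adjusted p = 3.5e-11), the TCA cycle 1 fall (8 adjusted over the list alone; 2.98e-10), peroxisomal beta-oxidation 1 (10; 3.25e-06) and histones with cyclins 2 (3; 0.00213). Heat shock chaperones (4.2e-05) and phosphate (0.0225) had 0 past limma, and these 6 lists had adjusted p = 0.431 with an estimated correlation. Ribosome biogenesis had 2 fall (3 down and 1 up adjusted over the list alone; adjusted p = 0.00013) and ergosterol 1 (8 adjusted over the list alone; 0.0234), while ATP synthase (1.91e-05), the respiratory chain (0.000935) and mitochondrial ribosomal proteins (0.0225) had 0 past limma, with 1, 3 and 0 falling adjusted over the list alone. These 5 had adjusted p = 0.544 with an estimated correlation.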

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

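The tests of non-specific signal and of RNA degradation, the upper bound used for the ribosomal RNA ratio, and camera on differences between time points were chosen only after the results were seen. Differences between time points share samples, and 4 h is 1 RNA sample.

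Of 100 genes in the text, 63 differed between time points in limma. The rule named genes partly for such differences, so this share is not a result. Over all 5449 genes, 144 differed at 2 h against 1 h, 639 at 4 h against 1 h and 47 at 4 h against 2 h. The largest log2 difference of each of the 63 among those past the test follows. Lower at 2 h than at 1 h were RNP1 (-1.96), ECM11 (-1.96), GAT3 (-1.86), HES1 (-1.57), PAU9 (-1.04), MEK1 (-0.98), SPO20 (-0.75) and STD1 (-0.53). Lower at 4 h than at 1 h were ADH2 (-2.33), PFS1 (-2.18), PHO92 (-2.01), YDL159W-A (-1.98), POL30 (-1.93), RRP1 (-1.92), RPL22A (-1.84), RPS9B (-1.69), RPA43 (-1.65), SCW10 (-1.61), RNR1 (-1.54), SPS1 (-1.52), RKI1 (-1.48), RPL8A (-1.38), SFC1 (-1.34), SIP18 (-1.30), SNZ3 (-1.27), RPS0A (-1.27), SIT1 (-1.17), SPB1 (-1.14), ADE17 (-1.10), PUF6 (-1.09), ERG4 (-0.91), GPP1 (-0.74), IMD3 (-0.67), CTA1 (-0.64), RPL37A (-0.64), ACS1 (-0.62), ASN2 (-0.57), PMA1 (-0.55) and RPL36A (-0.39). Higher at 4 h than at 1 h were OPT1 (1.40), STR3 (1.39), SUL2 (1.37), YKL068W-A (1.24), MUP1 (1.11), MET28 (0.87), PIR3 (0.82), FUI1 (0.81), COQ6 (0.65), MET8 (0.65), CPD1 (0.61), MDJ1 (0.61), YER053C-A (0.60), PDR15 (0.60), NSR1 (0.59), PDR3 (0.58) and UGA4 (0.51). Between 2 h and 4 h MF(ALPHA)1 (-2.74), INO1 (-1.93), ICL1 (-1.35), ECM13 (-1.07) and ACO1 (-0.68) were lower, and MUP3 (0.86) and SNU13 (0.67) higher. At 4 h PFS1 and MF(ALPHA)1 stood below the mean of the lacking LEU2, so the size of their differences is uncertain.

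By camera 16 lists differed between time points, none of them with an estimated correlation. Among the comparisons camera called, the largest median was at 4 h against 1 h for sulfur (0.61), ribosomal proteins (-0.45), ribosome biogenesis (-0.44), peroxisomal beta-oxidation (-0.41), trehalose and glycogen (0.35), the TCA cycle (-0.28), heat shock chaperones (0.28), histones and cyclins (-0.26), glycolysis and fermentation (0.11) and mitochondrial ribosomal proteins (-0.10). It was at 4 h against 2 h for gluconeogenesis (-0.33), ATP synthase (-0.25), the respiratory chain (-0.11), phosphate (-0.0935) and ergosterol (-0.0312), and at 2 h against 1 h for meiosis (-0.52). The ribosomal RNA control probe sets, outside the genes tested, lay above both controls on every treated array, by a mean of 1.25 at 1 h, 2.36 at 2 h and 2.27 at 4 h.

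Most genes called higher at 1 h were dim, 135 of 189, and none of the explanations weighed is excluded. Signal of no particular transcript cannot be told apart, since the genes the strain lacks, whose mean change was -0.137 (SE 0.093), are only 3 and lie near the floor, where RMA holds differences down. Material from the whole genome, such as DNA, cannot be told apart either. Of the 542 dimmest genes, 50.7% were higher and 17.9% lower in both 1 h arrays than in both controls, where chance gives 16.7% each way. The former share (95% interval 46.4 to 55, with genes taken as independent) lies between what such material would need and what would exclude it. A meiosis programme is argued against for its list as a set. The median of the list lay at percentile 52.2 of lists matched on level, which by the prediction written beforehand counts against it. The strain is also haploid, which this test did not use. That prediction did not weigh members that go both ways. Here 15 values lay above 0 and 10 below, and 6 of the 25 rose, so the median does not decide for single members. TFM or time itself, which the design names, may also raise dim genes and was not tested apart.

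Of 95 ribosome biogenesis genes 28 rose at 1 h, and the list had adjusted p = 0.64 with an estimated correlation. Ribosomal RNA signal as the whole cause is argued against on these arrays. Both 2 h replicate 2 and the 4 h sample had more of that signal than either 1 h array. The higher of their list medians was 0.482 of the lower 1 h median, where at least 1 was needed. The 95% interval of that ratio over resampled genes was 0.333 to 0.659, and the stricter bound of 0.5 written beforehand lies inside it. The interval does not measure the spread between RNA samples. Within each replicate pair, the array with more ribosomal RNA signal had the higher list median. Those medians were -0.07 and 0.07 in the controls, 0.41 and 0.52 at 1 h and 0.15 and 0.20 at 2 h. A partial contribution of that signal is therefore not excluded. RNA degradation cannot be told apart, since the 3' minus 5' difference changed by -0.064 and lay between the controls on both 1 h arrays. Control replicate 1 had the highest difference of the 8 arrays, 1.37. TFM and time since time zero remain open and untested.

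Of 127 ribosomal protein genes 37 fell at 4 h, and the list had adjusted p = 0.452 with an estimated correlation. Compression of bright probe sets is argued against, since the lowest median of 10000 lists matched on level was -0.078 and the list's was -0.347. Cross-hybridisation between paralogous copies is argued against, since 18 single-copy genes had a median of -0.427 and 109 paralogous genes -0.335. The 95% interval of the former, over resampled genes and not RNA samples, was -0.618 to -0.307. TFM and time since time zero remain open and untested, and the pattern rests on 1 RNA sample.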

How the results depend on the processing

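The filter at the level of the lacking genes and camera on differences between time points were chosen after seeing the data. Counts are given as higher and lower. The 102 calls on genes named in the text gave 1608 values under alternatives: 1254 kept direction and threshold, 354 kept direction but no longer passed, and 0 reversed. Robust priors and the mean of probe sets left each count within 1.5 times. Causes of the changes were not tested, except that fewer samples, fewer genes or a different shared spread enter some fits. Arrays give no depth; dim signal limits the 1 h calls.

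The trended prior gave 10 and 33 at 2 h, 71 higher at 4 h, 34 and 41 in the mean of 1 h and 2 h, 21 higher at 2 h against 1 h, 334 higher at 4 h against 1 h, 9 and 99 at 4 h against 2 h and 610 in the F test. Genes above the 25th percentile gave 63 higher at 1 h, 7 and 20 at 2 h, 64 higher at 4 h, 26 and 35 in the mean, 52 lower at 2 h against 1 h, 284 higher at 4 h against 1 h and 11 and 80 at 4 h against 2 h; the hexose transporter median at 1 h reversed to -0.18 (adjusted p = 0.564, against a range of medians up to 0.39). Median centring gave 53 lower at 1 h, 2 lower at 2 h and 7 and 4 in the mean. Quantile normalisation gave 143 lower at 1 h, 0 and 0 at 2 h, 25 and 125 at 4 h, 50 higher at 2 h against 1 h and 3 higher at 4 h against 2 h. Fits of only the groups compared gave 24 and 3 at 1 h and 4 and 11 at 2 h. At least 2-fold, the counts were 67 and 5 at 1 h, 0 and 3 at 2 h, 7 and 35 at 4 h, 1 and 5 in the mean, 1 and 41 at 2 h against 1 h, 112 at 4 h against 1 h (7 higher, the rest, 1.1e+02 when rounded, lower), 1 and 17 at 4 h against 2 h and 89 in the F test. List shifts, 10, 12 and 7 at 1, 2 and 4 h, became 0, 0 and 0 with an estimated correlation and 0, 0 and 9 by fry. With an estimated correlation camera has 3 residual degrees of freedom, so it could hardly pass any list. Meiosis at 2 h went from camera's adjusted p = 3.12e-05 to 0.404 though its estimated correlation was -0.0244. For that list the loss therefore does not show that correlation between genes made the shift. Other lists had estimated correlations well above the preset 0.01. They were 0.737 for ATP synthase, 0.555 for the respiratory chain, 0.36 for ribosomal proteins, 0.337 for sulfur and 0.236 for ribosome biogenesis. For such lists camera's p-values at the preset may be too small. Their losses do not tell correlation apart from few degrees of freedom.

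Samples with the same replicate number deviated with correlations of 0.0959, 0.19 and 0.0333. These are low, but they cannot show that the samples are unpaired, so pairing stays unknown. With the replicate block the counts were 340 and 154 at 1 h, 0 and 0 at 2 h, 99 and 65 in the mean, 20 and 281 at 2 h against 1 h, 2 and 21 at 4 h against 2 h and 541 in the F test; of the list calls, that of mitochondrial ribosomal proteins at 2 h was lost (median -0.07, adjusted p = 0.0789). The random block over the 8 arrays could not be fitted, because the RNA sample and the group coincide at 4 h.

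Leaving out 1 array gave ranges of 1 to 430 higher and 0 to 575 lower at 1 h, 0 to 4 and 0 to 20 at 2 h, 2 to 82 and 16 to 271 at 4 h, 0 to 136 and 0 to 147 in the mean, 0 to 259 and 0 to 304 at 2 h against 1 h, 7 to 649 and 93 to 678 at 4 h against 1 h, 0 to 11 and 0 to 65 at 4 h against 2 h, 1 to 836 in the F test, and 6 to 10, 10 to 12 and 7 to 9 lists at 1, 2 and 4 h. A lone sample left in a group was assumed to vary like the others. Its group then added nothing to the shared estimate of spread, also in comparisons that do not use that group.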

Other observations

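One of the tests here, on a list of osmotic stress genes, was chosen after the falls of single genes had been seen, but its prediction was written before the list's values. Several of the genes that led the falls are known to respond to Hog1, the kinase of the high-osmolarity pathway: STL1, GPD1, GPP1, CTT1, PHM7 and FMP48. At 2 h and 4 h PHM7 stood at -2.06 and -1.28 and FMP48 at -1.39 and -0.94, without passing the test. A hypothesis is that the osmotic stress response was lower after time zero. Of 12 other genes of that response, chosen from general knowledge and including HOR7, which is also in the general stress list, 11 were measured; 10 lay below 0 at 1 h and 0 passed limma. Their median at 1 h was -0.21, at percentile 0.2 of 10000 lists matched on level, whose central range was -0.13 to 0.09. Those lists were drawn gene by gene, so their range makes no allowance for genes of a shared response moving together. The sample medians were -0.28 and -0.23 at 1 h, -0.20 and -0.22 at 2 h and -0.03 at 4 h, against 0.05 and -0.05 in the controls. The median is consistent with the hypothesis at 1 h, where the percentile was 0.2, but with no solvent control at later times it cannot separate TFM from time, from handling at time zero or from the solvent.

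The seripauperin (PAU) genes, a family of cell wall proteins near the chromosome ends, were looked at after 3 of them had been named. Of 13 measured, 6 rose at 1 h and 0 fell, with medians of 0.79 at 1 h, -0.01 at 2 h and 0.11 at 4 h. In limma 0 rose at 2 h or 4 h. Their median level lay at percentile 29.5 of all genes, and the 545 genes around that level had a median change of -0.04 at 1 h. Their copies are nearly identical, so the counts do not say how many members changed.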
